A study of Mus musculus with 3 samples.

How the data were processed

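Kidney cells of male mice were measured in 3 libraries, 1 each from a young (3 to 4 months), an aged (20 months, vehicle) and an aged D+Q (20 months) group. Per the labels, tissue was digested with collagenase II, passed through a strainer, freed of red blood cells by lysis, and made into 3′ single-cell libraries on the MobiCube platform for paired-end Illumina NovaSeq sequencing. The deposited matrices hold raw UMI counts per gene and barcode, made by the authors and not normalised. The aligner and the rule that selected barcodes are not given in the sources used here. The lowest total per barcode was 1561 counts in young, 1416 in aged and 1451 in aged D+Q, so barcodes had been selected before deposit. The authors' notes name 2 mouse genome builds without their roles, so no coordinates are given. The files list 33696 genes, of which 52 share a symbol with another and were kept apart by identifier.

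Barcodes with over 50% mitochondrial counts were left out, which were 385 young, 82 aged and 149 aged D+Q barcodes, and 0 barcodes had under 200 genes. Doublets were scored per library with Scrublet in scanpy. Its automatic threshold called 0 barcodes in each library, under the 0.5% below which it was taken not to have worked. Barcodes above the score quantile of an expected rate of 0.8% per 1000 barcodes were therefore left out, which removed 532, 253 and 432 barcodes. The cells kept were clustered together on 2000 variable genes, 30 principal components, 15 neighbours and a Leiden resolution of 1, without batch integration, into 25 clusters. Tools were Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with R 4.3.3 and edgeR 4.0.16 for TMM scaling as an alternative.

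Cell names were rebuilt from markers of 20 classes fixed before the data were examined, and a difference from the study's own cell types may come from this. A cluster was named when at least 3 markers of a class had 10 counts and 0.25 of their highest cluster level, no other class reached 0.75 of its mean relative level, and its leading 10 genes held no more markers of another class. Haemoglobin genes did not count as markers in this rule. Cluster 4, led by haemoglobin and mitochondrially encoded genes, was therefore named proximal tubule-like. It held 491 young, 276 aged and 578 aged D+Q cells, with a median of 37.5% mitochondrial counts. Cluster 20, named thick ascending limb-like, had a median of 39.3% mitochondrial counts. A cluster with 0 of its class's markers among those 10 genes also stayed unnamed where they lay, at the median, over 16-fold above the other clusters, or where 3 of them led such a cluster. The thresholds of this rule were set after the data were seen. The last condition kept out cluster 7 (4.01% of young, 4.59% of aged and 4.49% of aged D+Q cells), cluster 19 (0.234%, 0.949% and 0.121%) and cluster 22 (0.286%, 0.439% and 0.523%). Clusters with markers of 2 classes also stayed unnamed. Among them was cluster 10, with endothelial and stromal markers and led by genes that include Csmd1 and Robo2 (7.50%, 6.82% and 6.05%). All unnamed cells made up 12.9% of young, 13.8% of aged and 11.8% of aged D+Q cells. Named classes with at least 50 cells in every library were compared, which gave 5 classes. Values within immune cells were planned but are not given, because no immune class could be named.

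Counts were summed per library and class and scaled by the total of the class to CPM. Log2 ratios used a prior of 0.5 counts, and genes needed at least 30 counts over the libraries and a mean of 5 CPM. Levels have exact Poisson intervals, ratios exact conditional binomial intervals and shares of cells exact Clopper-Pearson intervals, all at 95% and covering counting error only. A count of 0 was given the limit of 3 counts. For shares of cells with a UMI, cells were thinned to 1000 UMIs by 1 random draw per setting. Genes were named by a rule fixed before the data were examined: the 6 largest ratios in each direction in proximal tubule-like cells and 2 in each other class, per comparison. Such a gene had at least 30 CPM and 20 counts in the higher library and a ratio interval excluding 1.5-fold, and outside the proximal tubule a level of at least 50% of that in all cells of the library. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and sex-linked marker genes, and genes with provisional names, were left out of the naming. Some genes that the rule named are not reported here. For gene lists, the plan was to name the 2 to 4 members with the largest absolute ratio. The text names fewer or none for many lists, and more for the injury list. Sizes are counted at 1.5-fold.

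The 29 gene lists, fixed before the data were examined, hold 718 symbols, of which 701 are in the files. Each list's median was set beside 10000 random lists matched over 20 expression bins, as a description of these libraries, with a range from 200 Poisson redraws. The 2 comparisons, aged against young and aged D+Q against aged, share the aged library, so draws from 1 profile and splits of the aged cells, 20 of each, stand beside values that combine them. With 1 library per group there was no test.

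The steps were tested on simulated data with 10799 genes, of which 200 were changed. Part of these were set 2-fold apart and the others between 1.5-fold and 2-fold. Recovery was computed for the 2-fold genes only. The intervals held the true ratio for 95.3% of genes, and 99% of the 2-fold genes and 0.471% of unchanged genes were at least 1.5-fold apart with an interval excluding 1. In the first set the median error for genes set 2-fold lower was −0.06, beyond the limit of 0.05 chosen in advance. The limit was then applied to the mean over 20 sets, which was −0.0071 for genes set 2-fold higher and −0.0023 for genes set 2-fold lower. Of unchanged 20-gene lists, 3.5% lay in the outer percentiles. With D+Q set to the midpoint, 52.0% of the genes found at least 1.5-fold apart with an interval excluding 1 were nearer to young. These include unchanged genes that reached the limits through counting error.

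Alternatives were a mitochondrial limit of 25%, at least 500 genes per cell, no doublets left out, a resolution of 2, each library clustered alone, median-of-ratios and TMM scaling, mitochondrially encoded genes left out of the total, a mean over cells, a prior of 5 counts, no floor, a 2-fold rule, and thinning to 500 UMIs or none. After the data were seen, 3 more were added: without cluster 4, clusters 0, 5 and 8 alone, and the injury list without S100a6, Krt18 and Krt19.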

Results

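Single-cell 3′ transcriptomes were collected from the kidneys of male mice in 3 groups with 1 library each. The young group was 3 to 4 months old, the aged group was 20 months old and received vehicle, and the aged D+Q group was 20 months old and received D+Q. The series describes this treatment as senolytic, that is, aimed at clearing senescent cells; D+Q usually stands for the kinase inhibitor dasatinib and the flavonoid quercetin. The young library held 8615 barcodes and 24346733 UMI counts, the aged library 6027 barcodes and 13944270 counts, and the aged D+Q library 8037 barcodes and 21058975 counts. The median barcode had 2391, 1883 and 2299 counts, in that order. After filtering, 7698 young, 5692 aged and 7456 aged D+Q cells were kept. Where a value comes from 20 draws or divisions, the parentheses give the lowest and highest value. All other intervals are 95% intervals that cover counting error only. With 1 library per group, no difference below has a replicate check and no test was possible. "Higher" and "lower" therefore describe these libraries.

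Most cells of each library were proximal tubule-like, the class that expresses the transporters of the first nephron segment. They made up 63.0% of young cells (61.9 to 64.0), 69.7% of aged cells (68.5 to 70.9) and 68.4% of aged D+Q cells (67.4 to 69.5), with exact Clopper-Pearson intervals. Endothelial-like cells were 8.29% of young cells (7.68 to 8.93), 6.38% of aged cells (5.76 to 7.04) and 6.24% of aged D+Q cells (5.70 to 6.81). Thick ascending limb-like cells were 4.91%, 3.13% and 5.23%, and distal convoluted tubule-like cells 3.48%, 2.79% and 3.18%. Connecting tubule and principal cell-like cells were 1.88%, 1.34% and 1.99%. The remaining named classes were small. Urothelium-like cells were 1.98% of young cells (1.68 to 2.31), 0.246% of aged cells (0.135 to 0.412) and 1.03% of aged D+Q cells (0.816 to 1.29), and adipocyte-like cells 1.01%, 0.211% and 0.0805%. Intercalated cell-like cells were 1.30%, 0.791% and 0.684%, thin limb-like cells 0.624%, 0.439% and 0.966%, podocyte-like cells 0.533%, 0.527% and 0.268%, and stromal-like cells 0.104%, 0.615% and 0.121%. The stromal-like class depended on the processing, with 0 cells in each library with no doublets left out and at a resolution of 2. With each library clustered alone it held 0 young, 35 aged and 0 aged D+Q cells. Stromal markers were also found in the larger unnamed cluster 10, which this share leaves out. Leukocytes formed a cluster of 44 young, 50 aged and 36 aged D+Q cells led by Lyz2, Dock2 and Ptprc, which carried markers of several immune types and stayed unnamed, so shares within immune cells are not given.

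**Figure D1:**
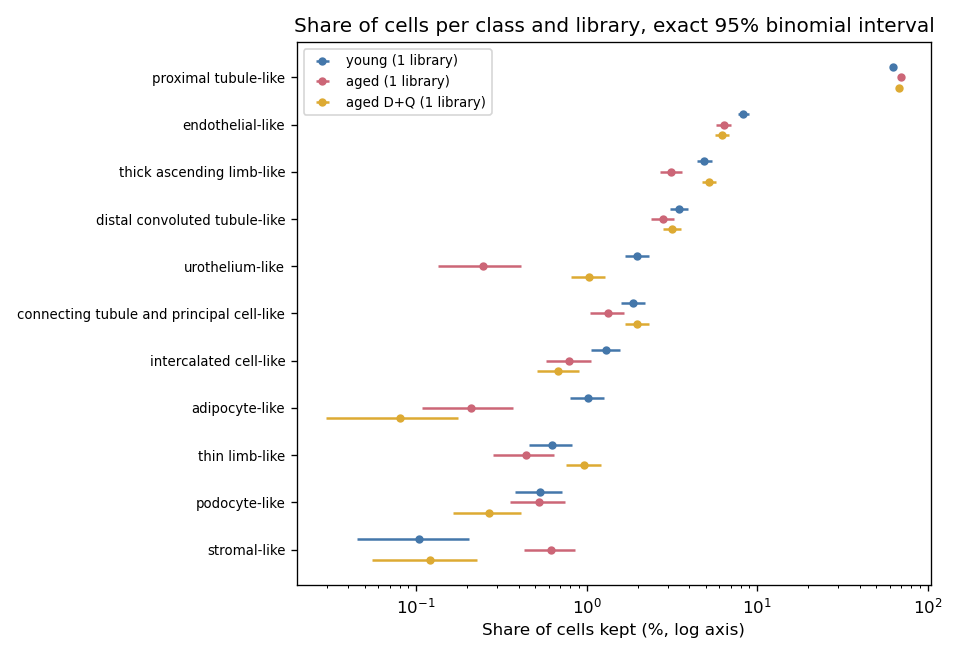
Share of the cells kept in each named class (horizontal log axis, percent) for the young, aged and aged D+Q libraries, 1 library each, with exact 95% binomial intervals that cover counting error only. The urothelium-like share lay between 0.246% in the aged and 1.98% in the young library, a wider ratio than for the proximal tubule-like share.

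Proximal tubule transcripts were also counted in other classes, which free RNA or mixed droplets can give, and this bears on every class outside the proximal tubule. No background profile was measured, so the source was not tested. Slc34a1, the phosphate transporter of the proximal tubule, reached in endothelial-like cells 65.9% of its proximal tubule-like level in the young, 90.8% in the aged and 54.4% in the aged D+Q library. Kap, an abundant proximal tubule transcript, went the other way, at 64.8%, 50.1% and 74.4% in endothelial-like and 93.1%, 78.6% and 105% in thick ascending limb-like cells. Free RNA at 1 share per library would not give this if its makeup were that of proximal tubule-like cells. That makeup is not known here, so free RNA stays open. Summed over the list of proximal tubule transport genes, endothelial-like cells held 66.4%, 78.3% and 57.3% of the proximal tubule-like level, and thick ascending limb-like cells 50.7%, 62.5% and 45.9%. Distal convoluted tubule-like cells held 39.1%, 61.2% and 31.1%, and connecting tubule and principal cell-like cells 58.3%, 45.0% and 35.0%.

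**Figure D2:**
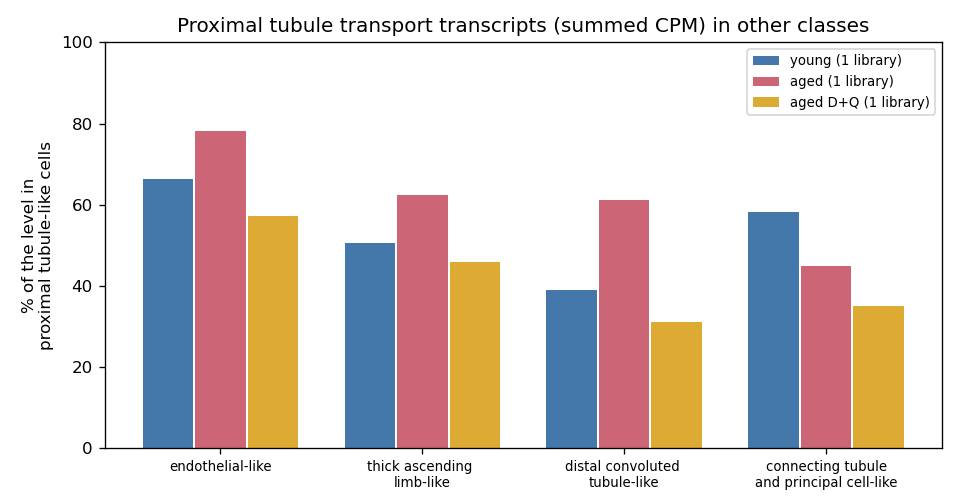
Summed level (CPM) of the proximal tubule transport genes in 4 other classes, as a percent of the level in proximal tubule-like cells of the same library, 1 library per bar. In endothelial-like cells the value was 66.4% in young, 78.3% in aged and 57.3% in aged D+Q.

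The first comparison set the aged against the young kidney, which addresses how ageing alters kidney cells. In proximal tubule-like cells of the aged library, genes of peroxisomal and mitochondrial fatty acid use were lower. Cyp4a14, a fatty acid omega-hydroxylase, was at 192 CPM (184 to 200) in young and 19.1 CPM (16.2 to 22.4) in aged cells, a log2 ratio of −3.32 (−3.57 to −3.09). Pdk4, which restrains pyruvate oxidation, had a log2 ratio of −2.78 (−3.26 to −2.36), and Ehhadh, a peroxisomal beta-oxidation enzyme, −1.90 (−2.01 to −1.80). Of 41 measured fatty acid oxidation genes, 9 were at least 1.5-fold lower in aged and 0 at least 1.5-fold higher, with a median log2 ratio of −0.20 (−0.22 to −0.08).

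Slc7a12, an amino acid transporter known for higher levels in female kidneys, was at 1.47 CPM (0.869 to 2.32) in young and 81.0 CPM (74.9 to 87.5) in aged cells, a log2 ratio of 5.75 (5.12 to 6.55). The adhesion receptor Adgrb3 followed at 3.94 (3.69 to 4.21), the protocadherin Pcdh11x at 3.25 (2.85 to 3.71), the cytochrome P450 Cyp2d12 at 2.12 (2.01 to 2.23) and the protease inhibitor Serpina1a at 2.05 (1.73 to 2.38). The teneurin Tenm3 was at 9.69 CPM in young and 41.7 CPM in aged cells. Among the other genes with low ratios were the calcium-binding protein S100a6, at −3.04 (−3.38 to −2.74), and the carbonic anhydrase Car3, at −1.81 (−2.20 to −1.45). S100a6 also led 1 of the urothelium-like clusters and Car3 the adipocyte-like cluster, and both classes had smaller shares in the aged library. Urothelial markers summed to 58.0 CPM (53.8 to 62.4) in young, 2.86 CPM (1.81 to 4.29) in aged and 14.6 CPM (12.6 to 16.9) in aged D+Q proximal tubule-like cells. The urothelium-like class depended on the processing, with 152 young, 14 aged and 77 aged D+Q cells, but 61, 0 and 2 with no doublets left out, and 140, 0 and 77 with each library clustered alone. The identifiers in the files were ENSMUSG00000039710 for Slc7a12, ENSMUSG00000033569 for Adgrb3, ENSMUSG00000034755 for Pcdh11x, ENSMUSG00000096852 for Cyp2d12, ENSMUSG00000031561 for Tenm3 and ENSMUSG00000066366 for Serpina1a. Those of the lower genes were ENSMUSG00000028715 for Cyp4a14, ENSMUSG00000001025 for S100a6, ENSMUSG00000019577 for Pdk4, ENSMUSG00000022853 for Ehhadh and ENSMUSG00000027559 for Car3. The Cyp4a, Cyp2d and Serpina1 genes have close paralogues, and how the authors' counting divided reads among them is not given in the sources used here.

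**Figure D3:**
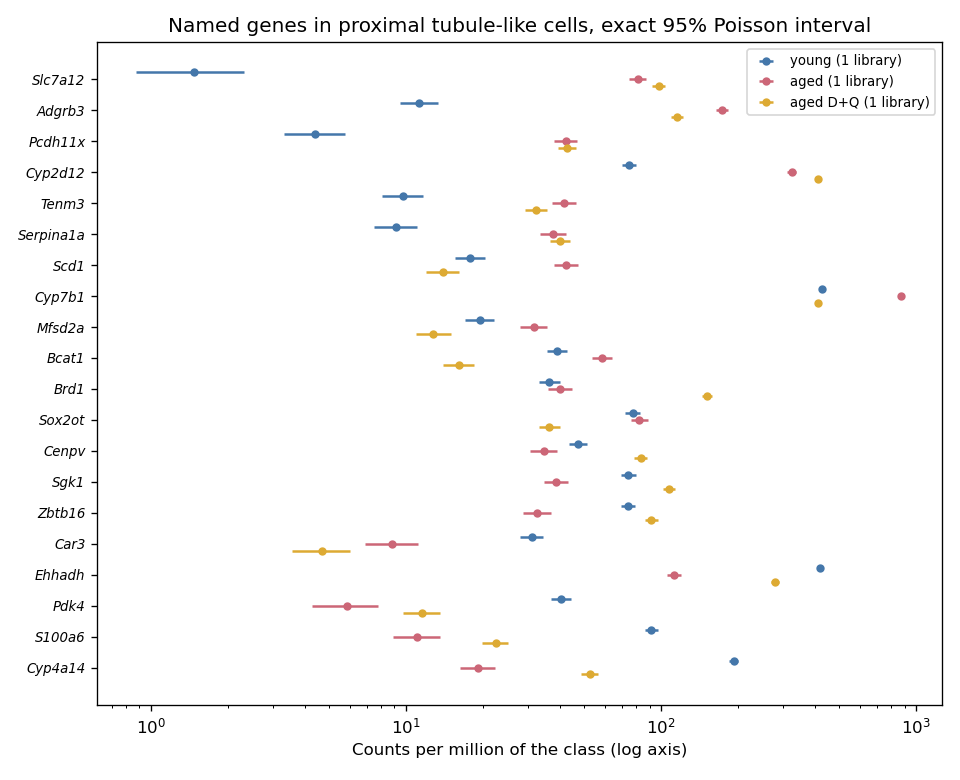
Levels of 20 genes named by rule in proximal tubule-like cells (horizontal log axis, CPM of the class) in the young, aged and aged D+Q libraries, 1 library each, with exact 95% Poisson intervals that cover counting error only. Slc7a12 was at 1.47, 81.0 and 97.8 CPM and Cyp4a14 at 192, 19.1 and 52.6 CPM, in that order.

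Among the gene lists fixed before the data were examined, cell cycle arrest and senescence genes had a median log2 ratio of 0.29 (0.21 to 0.39), at percentile 99.2 among 10000 random lists matched on expression, as a description of these libraries. Of its 13 measured members, 3 were at least 1.5-fold higher in aged (Btg2 1.02, Gdf15 1.01 and Zmat3 0.77) and 0 lower. Elsewhere this list's median was 0.06 (−0.18 to 0.15, percentile 52.4) in endothelial-like and −0.03 (−0.22 to 0.48, percentile 17.2) in thick ascending limb-like cells. In distal convoluted tubule-like cells it was −0.27 (−0.58 to 0.25, percentile 1.63). The secretory phenotype list, which shares Gdf15, had a median of −0.06 (−0.14 to 0.02), with Serpine2 at 1.85, Gdf15 at 1.01, Angptl4 at −0.87 and Plau at −0.83. Without an expression floor this list's median turned to 0.18. Tubular injury genes went both ways. Of 19 measured, 6 were higher, among them complement C3 at 1.82 and ceruloplasmin (Cp) at 1.28, and 4 were lower, namely Krt19 at −3.31, S100a6 at −3.04, Krt18 at −2.85 and Anxa2 at −0.64, with a median of 0.23 (−0.16 to 0.39). C3 also led the stromal-like cluster, which was 0.104% of young, 0.615% of aged and 0.121% of aged D+Q cells, and RNA from such cells was not separated. Krt18, Krt19 and S100a6 are also abundant in urothelium-like cells, at 953, 1329 and 2388 CPM in the young library. Mitochondrially encoded transcripts had a median of −0.38 (−0.39 to −0.36), beside a median mitochondrial share per cell of 5.53% in young and 4.40% in aged cells of the class.

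Antigen presentation class II genes were higher in aged, with a median of 0.56 (0.44 to 0.70) and 3 of 6 at least 1.5-fold higher, including H2-Aa at 0.96, H2-Eb1 at 0.95 and Cd74 at 0.65. The leukocyte gene Lyz2, looked at after these values were seen, was at 2.93 CPM in young, 8.32 CPM in aged and 2.70 CPM in aged D+Q proximal tubule-like cells, and the unnamed cluster led by Lyz2, Dock2 and Ptprc was 0.572%, 0.878% and 0.483% of cells. Free RNA of leukocytes was not separated from the class II values. The class II median was 0.61 in endothelial-like, 0.63 (−0.01 to 1.09) in thick ascending limb-like and −0.62 (−1.11 to 0.10) in distal convoluted tubule-like cells. Segment S3 genes had a median of 0.23 (0.21 to 0.26), with Cyp7b1, an oxysterol hydroxylase, at 1.02 and Slc22a7 at −0.76. Proximal tubule transport genes had a median of 0.13 (0.11 to 0.16), with 3 of 44 at least 1.5-fold higher, among them Abcc4 at 1.13. Male-biased proximal tubule genes had a median of 0.16 (0.13 to 0.22), and the 5 female-biased genes ranged from −3.36 for Akr1c18 to 5.75 for Slc7a12, with a median of 0.45 (0.37 to 0.52). Matrix and fibrosis genes had a median of −0.21, with Col8a1 at −1.25, and macrophage complement and lipid genes one of −0.21 (−0.29 to −0.13), with C3 at 1.82 and Lpl at −0.99. Without an expression floor the macrophage list median turned to 0.81. Interferon response genes stood at −0.19 (−0.37 to −0.05), class I genes at −0.16 (−0.23 to 0.05) and unfolded protein response genes at −0.10 (−0.16 to −0.02). The dasatinib kinase target list had a median of 0.27 (0.14 to 0.41), with Csf1r at 0.64. Csf1r was also a macrophage and monocyte marker in the naming of clusters, and free RNA of leukocytes was not separated from its value. The list of survival factors of senescent cells stood at 0.15 (0.04 to 0.23), with Bcl2 at 0.80, and the longevity-associated list at 0.17 (0.09 to 0.21), with Tfeb at 0.69. The median of all genes was 0.07. Other list medians were those of the antioxidant list at 0.10, cytosolic ribosomal proteins at 0.11, segment S1 at 0.03, proliferation at 0.03, gluconeogenesis at −0.02, the nuclear-encoded respiratory chain at −0.04, the immediate early list at −0.04 and the endothelial activation list at −0.08. Median-of-ratios and TMM scaling lowered every gene alike by about the median of all genes, so the signs for segment S1 and proliferation depended on the scaling. The direction turned for cytosolic ribosomal proteins under a mean over cells, and for gluconeogenesis and the respiratory chain at a mitochondrial limit of 25%.

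**Figure D4:**
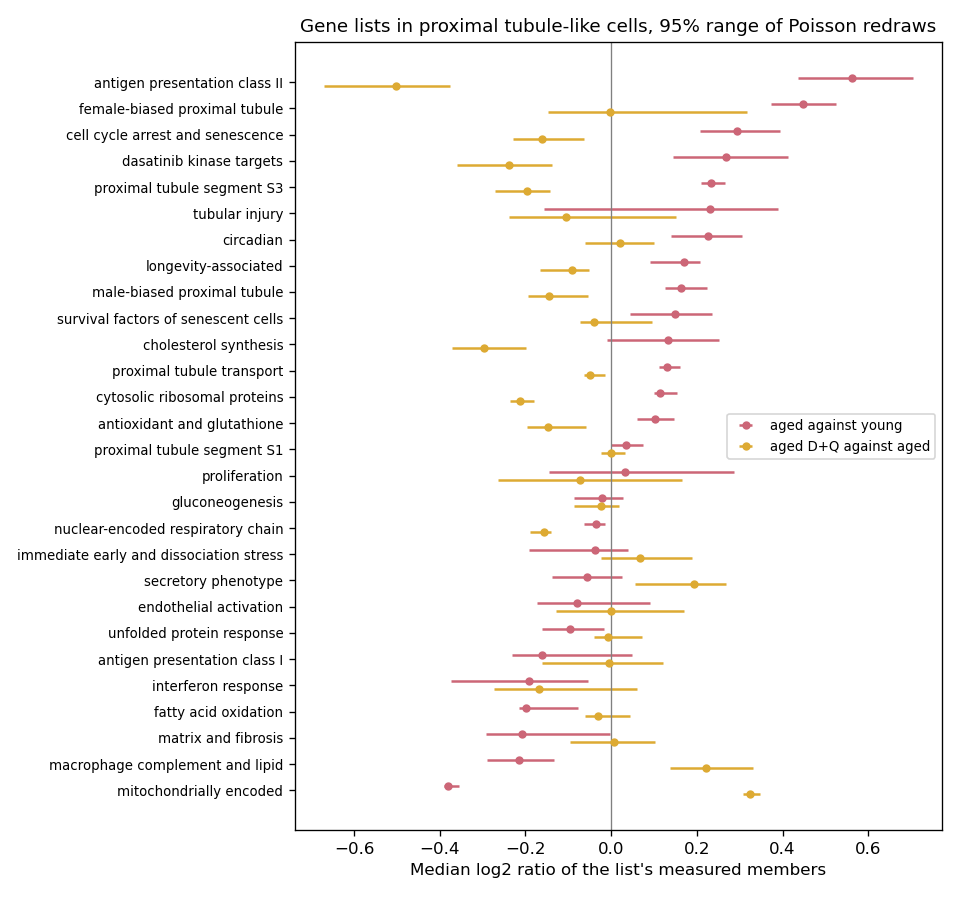
Median log2 ratio of the measured members of 28 gene lists in proximal tubule-like cells, aged against young and aged D+Q against aged, 1 library per group, with the 95% range over 200 Poisson redraws of the counts. Fatty acid oxidation stood at −0.20 and antigen presentation class II at 0.56 in aged against young.

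Cdkn1a, which encodes the cell cycle inhibitor p21, was seen in few proximal tubule-like cells. Every cell was thinned to 1000 UMIs by 1 random draw, which left out 0 cells. Of the thinned cells, 0.474% of young (0.301 to 0.711), 0.302% of aged (0.156 to 0.528) and 0.392% of aged D+Q cells (0.240 to 0.605) had a UMI. Unthinned shares were 0.908%, 0.731% and 1.02%, and levels were 4.07, 4.97 and 4.29 CPM, at median depths of 2360, 1809 and 2301 counts. The intervals overlapped and the shares ran against the CPM values, so no order was detectable at this depth. Unthinned Cdkn1a shares in endothelial-like cells were 4.08%, 3.86% and 4.52%, with levels of 12.7, 13.9 and 16.5 CPM at median depths of 2802, 2632 and 2684 counts. Thinned, they were 1.25% (0.543 to 2.46), 0.275% (0.00697 to 1.53) and 1.51% (0.607 to 3.08), the aged value resting on 1 cell, so no order was read. Cdkn2a, which encodes p16, had 1 count in young and 0 counts in aged and aged D+Q proximal tubule-like cells. The count of 0 allows up to 0.0756% of aged and 0.0588% of aged D+Q cells with a UMI. Over all cells kept, 7 young, 1 aged and 2 aged D+Q cells had a Cdkn2a UMI.

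Different clusters held much of the proximal tubule-like class in the 2 libraries. Cluster 9, led by genes that include Cyp4a14 and Ehhadh, held 1603 of 4847 young and 90 of 3967 aged cells, and cluster 11, led by Cntnap5a, Anks1b and Cyp2j13, held 375 young and 1637 aged cells. In clusters 0, 5 and 8 alone the senescence list median was smaller, at 0.15, and the injury list median was within 0.01 of 0.

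In other classes, aged against young ratios stood beside the proximal tubule transcripts above, which differed between libraries and, for the summed transport genes, were larger in aged than in young in 3 of the 4 classes but smaller in connecting tubule and principal cell-like cells. In endothelial-like cells, Tagln and Acta2, contractile genes of smooth muscle and pericytes, had log2 ratios of −3.57 (−5.63 to −2.33) and −3.20 (−4.52 to −2.26), with 4 and 8 counts in the aged library. Both ratios were within 0.5 of 0 at a mitochondrial limit of 25%, and both were nearer to 0 with no doublets left out. Slc7a12, with 1 count in young cells, was at 5.79 (3.81 to 11.70) and Adgrb3 at 2.93 (2.38 to 3.55), both as in the proximal tubule-like class. The endothelial-like medians were −0.59 for interferon response genes, with 15 of 29 at least 1.5-fold lower, −0.47 for matrix and fibrosis genes, −0.43 for endothelial activation genes, −0.45 for immediate early genes and −0.94 for mitochondrially encoded genes, while proximal tubule transport genes stood at 0.32. The T cell cytotoxicity and exhaustion list had 5 measured members in these cells, with a median of 0.86. Tek, a member of the endothelial activation list and a marker that named the class, itself had a ratio of −0.97. That list also holds the class markers Kdr, Flt1, Plvap and Ehd3, so its median does not separate activation from class identity. The median of all genes was 0.05 in endothelial-like, 0.13 in thick ascending limb-like and 0.14 in distal convoluted tubule-like cells, and −0.06, −0.10 and −0.08 in D+Q against aged. Transport genes of the proximal tubule stood at 0.37 in thick ascending limb-like and 0.74 in distal convoluted tubule-like cells, and at −0.30 and −1.01 in D+Q against aged. In thick ascending limb-like cells Cyp2d12 had a ratio of 2.87 (2.33 to 3.47), the actin-severing protein gelsolin (Gsn) 2.31 (1.19 to 3.59), aldose reductase (Akr1b3) −3.04 (−5.56 to −1.64) and S100a6 −2.86 (−4.65 to −1.72). Akr1b3 and S100a6 were also leading genes of a urothelium-like cluster of 55 young, 0 aged and 2 aged D+Q cells. In distal convoluted tubule-like cells Adgrb3 had 0 counts in young and 29 in aged cells, Lrrc4c had a ratio of 4.61 (2.52 to 10.54), S100a6 −3.09 (−5.16 to −1.82) and the transcription factor Prox1 −2.65 (−5.20 to −1.20). In connecting tubule and principal cell-like cells Cyp2d12 was at 3.61 (2.65 to 4.87), while S100a6 and Bcl11b had 35 and 20 counts in young and 0 in aged cells. The median mitochondrial share of this class was 7.26% in young, 16.6% in aged and 13.9% in D+Q cells. In the other compared classes it was lower in aged than in young. At a clustering resolution of 2 the Bcl11b ratio was nearer to 0.

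The share of thick ascending limb-like cells in aged was 0.637 times that in young (0.530 to 0.763), that of endothelial-like cells 0.770 times (0.675 to 0.877) and that of proximal tubule-like cells 1.11 times (1.06 to 1.16). The ratio for distal convoluted tubule-like cells was 0.802 (0.655 to 0.980) and that for connecting tubule and principal cell-like cells 0.709 (0.530 to 0.942), and the direction of the latter reversed at a clustering resolution of 2, on 21 young and 38 aged cells. It was 0.448 at a mitochondrial limit of 25% and 0.454 with at least 500 genes per cell. These ratios share the denominator of all cells, which the larger proximal tubule-like share affects. Of the cells outside that class, endothelial-like cells were 22.38% in young (20.86 to 23.95) and 21.04% in aged (19.14 to 23.04), distal convoluted tubule-like cells 9.40% and 9.22%, and connecting tubule and principal cell-like cells 5.09% (4.31 to 5.96) and 4.41% (3.49 to 5.48), with overlapping intervals. Thick ascending limb-like cells were 13.3% (12.0 to 14.6) and 10.3% (8.92 to 11.9).

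The second comparison set the aged D+Q against the aged kidney, which addresses what the treatment alters in aged kidney cells. In proximal tubule-like cells of the D+Q library, the chromatin reader Brd1 was at 152 CPM (145 to 159) against 40.2 CPM (36.0 to 44.9) in aged cells, a log2 ratio of 1.91 (1.75 to 2.09). The glucocorticoid-responsive genes Zbtb16 and Sgk1 followed at 1.48 (1.29 to 1.68) and 1.47 (1.30 to 1.66), and the fatty acid genes Cyp4a14 and Ehhadh at 1.46 (1.21 to 1.72) and 1.31 (1.21 to 1.42). The branched-chain aminotransferase Bcat1 was lower in D+Q, at 16.1 against 58.6 CPM, a ratio of −1.86 (−2.11 to −1.62). The list medians of antigen presentation class II and cholesterol synthesis genes were below 0. Of their measured members, 2 of 6 and 1 of 18 were at least 1.5-fold lower.

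Other genes named by rule were Cenpv at 1.26 (1.07 to 1.46), the fatty acid desaturase Scd1 at −1.60 (−1.88 to −1.34), the lysolipid transporter Mfsd2a at −1.31 (−1.60 to −1.02), the long non-coding RNA Sox2ot at −1.17 (−1.34 to −0.99) and Cyp7b1 at −1.08 (−1.14 to −1.03). Young levels were nearer to D+Q than to aged for Scd1, at 17.8 CPM, and Cyp7b1, at 428 CPM, but not for Brd1, at 36.5 CPM. Slc7a12 was at 97.8 CPM in D+Q, near its aged level of 81.0 CPM. The identifiers were ENSMUSG00000022387 for Brd1, ENSMUSG00000066687 for Zbtb16, ENSMUSG00000019970 for Sgk1, ENSMUSG00000018509 for Cenpv, ENSMUSG00000030268 for Bcat1 and ENSMUSG00000037071 for Scd1. Mfsd2a was ENSMUSG00000028655, Sox2ot ENSMUSG00000105265 and Cyp7b1 ENSMUSG00000039519.

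Cell cycle arrest and senescence genes had a median log2 ratio of −0.16 (−0.23 to −0.06) in D+Q against aged, at percentile 10.2 among matched random lists, where the median of all genes was −0.06. Of its 13 members, 1 was at least 1.5-fold lower (Btg2, −0.76) and 0 higher. The secretory phenotype list had a median of 0.19 (0.05 to 0.27), with 2 of 16 higher, namely Tnfrsf1a at 0.64 and Angptl4 at 0.59. The direction of this median turned without an expression floor. Of 41 fatty acid oxidation genes, 3 were higher (Cyp4a14, Ehhadh, and Pdk4 at 0.97) and 0 lower, with a median of −0.03 (−0.06 to 0.04). Of 19 tubular injury genes, 3 were higher (Krt19 2.06, Krt18 1.66 and S100a6 1.01) beside the higher urothelial markers given above, and 3 lower (Cryab −0.76, C3 −0.70 and Tmsb10 −0.67), with a median of −0.11 (−0.24 to 0.15) whose direction turned at a clustering resolution of 2 and under a mean over cells.

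Class II genes had a median of −0.50 (−0.67 to −0.38), with H2-Aa at −0.92 and H2-Eb1 at −0.85, beside the smaller leukocyte cluster in D+Q. Cholesterol synthesis genes stood at −0.30 (−0.37 to −0.20), with Idi1 at −0.75, against 0.13 (−0.01 to 0.25) in the first comparison, where Lss was at 0.98 and Cyp51 at −0.81. Mitochondrially encoded genes stood at 0.32 (0.31 to 0.35), beside a median mitochondrial share of 5.54% in D+Q and 4.40% in aged cells of the class. Dasatinib kinase targets stood at −0.24 (−0.36 to −0.14), with 0 of 8 at least 1.5-fold apart. Cytosolic ribosomal proteins stood at −0.21 (−0.24 to −0.18), segment S3 genes at −0.20 (−0.27 to −0.14), interferon response genes at −0.17 (−0.27 to 0.06), turned at a clustering resolution of 2, with Iigp1 at −1.08, and the nuclear-encoded respiratory chain at −0.16 (−0.19 to −0.14). Antioxidant and male-biased genes were both at −0.15, and the macrophage complement and lipid list at 0.22 (0.14 to 0.33), with Lpl at 0.83. Without an expression floor this macrophage list median turned to −0.21. Other list medians were those of the longevity-associated list at −0.09, proliferation at −0.07, transport at −0.05, survival factors at −0.04 and gluconeogenesis at −0.02. Class I, unfolded protein response, segment S1, female-biased, matrix and endothelial activation lists lay within 0.01 of 0, and the immediate early list at 0.07. Median-of-ratios and TMM scaling raised every gene alike by about 0.06 here, so the signs of the transport, gluconeogenesis, survival factor and fatty acid oxidation medians depended on the scaling.

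Both comparisons use the same aged library, so opposite ratios arise in part by construction. Of 873 genes at least 1.5-fold apart between aged and young with a ratio interval excluding 1 (482 higher and 391 lower in aged), 37.9% had a D+Q level nearer to young than to aged on the log2 scale. The share was 36.1% of the genes higher in aged and 40.2% of those lower in aged, and 27.1% of the 192 genes at least 2-fold apart. When D+Q counts were drawn from the aged profile, the mean share was 0.389% over 20 draws. Such draws carry over the counting error of the aged counts, so a low share was fixed by the setting. It is not the value without a treatment difference. With all libraries drawn from 1 profile it was 65.0% (range 47.7 to 78.9 over 20 draws). This was above the observed share, but of a mean of 38.5 genes that reached the limits through counting error. When the aged cells were divided at random into equal parts, with 1 part in the place of D+Q, it was 18.3% (range 16.2 to 20.4 over 20 divisions). With separate aged cells for each ratio it was 36.0%.

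Across 10805 genes, which are not independent replicates, the ratios of the 2 comparisons had a Pearson r of −0.52 and a covariance of −0.0626. With all libraries drawn from 1 profile, r was −0.61 and the covariance −0.0135. With separate aged cells for each ratio, r was −0.34 and the covariance −0.0470. Without the rule on the interval, 483 genes were at least 1.5-fold higher in aged and 221 lower in D+Q, and 71 were in both lists. Of 391 genes lower in aged and 196 higher in D+Q, 99 were in both. Independent lists give 9.88 and 7.09, which is not the value without a treatment difference, since the aged library is shared. With 1 random part of the aged cells in the place of D+Q and the other as aged, at fewer counts each, they were 41.3 (30 to 59) and 70.7 (60 to 85) over 20 divisions. With all libraries drawn from 1 profile they were 2.4 and 6, and with separate aged cells for each ratio 71.8 (65 to 81) and 82.4 (73 to 92). Overlaps in like directions were 2 genes higher in both and 7 lower in both. Separate aged cells remove shared counting error but not what is particular to that 1 library, and part of each overlap can come from it.

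In endothelial-like cells the ratios of D+Q against aged stood beside proximal tubule transcripts that were lower in D+Q for the summed transport genes and higher for Kap, which was at 50.1% of its proximal tubule-like level in aged and 74.4% in D+Q. The early response gene Ier3 was at 2.20 (1.28 to 3.40) and Cd24a at 8.50 CPM in aged and 37.7 CPM in D+Q cells, while Ano4 was at −1.87 (−2.89 to −1.02) and Egfem1 at −1.81 (−2.79 to −0.97). Egfem1 was a leading gene of the connecting tubule and principal cell-like cluster. The endothelial activation list had a median of 0.79, with 9 of 14 at least 1.5-fold higher, among them Klf4 at 1.64 and Igfbp3 at 1.24. Tek, a member that is also a marker of the class, was at 1.16. As this list also holds the class markers Kdr, Flt1, Plvap and Ehd3, its median does not separate activation from class identity. Immediate early genes stood at 0.55, interferon response genes at 0.22, matrix genes at 0.23, mitochondrially encoded genes at 0.99, transport genes at −0.41 and the T cell list at −0.46. In thick ascending limb-like cells the basement membrane collagen Col4a1, with 3 counts in aged, was at 2.39 (0.95 to 4.93), Xylt1 at −2.13 (−2.98 to −1.35) and Dixdc1 at −1.98 (−3.11 to −0.96), and Plekha3 had 0 counts in aged and 27 in D+Q. In distal convoluted tubule-like cells Supt7l was at 3.22 (1.13 to 9.14) and Cyp2u1 at 2.74 (1.02 to 6.16), on 1 and 2 counts in aged, and the muscarinic receptor Chrm3 was at −2.61 (−4.00 to −1.55) and Hpd at −2.48 (−3.88 to −1.40). In connecting tubule and principal cell-like cells Klf6 was at 2.91 (0.84 to 8.83) and Slc7a12 at 2.85 (0.76 to 8.77), each on 1 count in aged, while Clec2h was at −2.63 (−3.94 to −1.56) and Ltc4s at −2.24 (−3.58 to −1.11). Hpd and Clec2h were among the leading genes of proximal tubule-like clusters. The Ltc4s ratio reversed with at least 500 genes per cell, where that of Klf6 was also nearer to 0.

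The share of thick ascending limb-like cells in D+Q was 1.67 times that in aged (1.40 to 2.01) and that of connecting tubule and principal cell-like cells 1.49 times (1.12 to 1.99). The thick ascending limb-like class included cluster 20, with a median of 39.3% mitochondrial counts and 39 aged and 136 D+Q cells. Its other cluster, 15, had a median of 7.30% and held 139 aged and 254 D+Q cells. Part of the 1.67 therefore rests on cells with many mitochondrial counts. The ratios were 0.978 (0.851 to 1.12) for endothelial-like, 0.982 (0.942 to 1.02) for proximal tubule-like and 1.14 (0.927 to 1.40) for distal convoluted tubule-like cells, so for these 3 classes a difference was not detectable at this depth. Of the cells outside the proximal tubule-like class, thick ascending limb-like cells were 16.6% (15.1 to 18.1) in D+Q, and connecting tubule and principal cell-like cells 6.29% (5.34 to 7.35), an interval that overlapped that of aged. With no doublets left out the endothelial-like ratio was 1.19. Among proximal tubule-like cells, cluster 9 held 394 and cluster 11 held 1758 of 5103 D+Q cells.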

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

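The gene family sums below were formed only after values of single genes had been seen, and no test of their cause was run. Both families were left out of the naming of genes, although their counts were part of the totals and of the ratios per class. No comparison used their sums over all cells, which were above the limit that a count of 0 allows and, in the 3 values set against young below, higher than in young. Immunoglobulin constant region genes and Jchain, 14 genes summed over all cells kept, were at 5.21 CPM (4.30 to 6.27) in the young, 180.7 CPM (173.5 to 188) in the aged and 92.95 CPM (88.7 to 97.4) in the aged D+Q library. The ratio to young was 34.6 (28.7 to 42.2) in aged and 17.8 (14.7 to 21.8) in aged D+Q. At least 1 such UMI was counted in 82 young, 1137 aged and 909 aged D+Q cells, and Igha alone was at 0.369, 65.4 and 27.3 CPM. The 10 cells with most immunoglobulin counts held 35.4% of them in young, 33.39% in aged and 32.65% in aged D+Q. Haemoglobin genes, 8 summed, were at 331.9 CPM in young, 574 CPM (561 to 587) in aged and 293 CPM in aged D+Q, although red blood cells had been lysed. The 10 cells with most haemoglobin counts held 53.4% of them in young, 26.6% in aged and 58.4% in aged D+Q, so these levels rest in part on few cells. With 1 library per group, age, treatment and the single preparation of each library stay open.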

How the results depend on the processing

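Results without cluster 4, in clusters 0, 5 and 8 alone, and for the injury list without S100a6, Krt18 and Krt19 come from alternatives chosen only after the results were seen. No paired analysis was possible because each group had 1 library. Of 1909 alternative values for 178 results, 1655 lay within the counting interval or redraw range of the value reported, 234 moved beyond it and 20 reversed. A reversal was counted only where the interval or range of the reported value excluded no difference, so some medians near 0 turned direction without being among the 20. Among named genes, 583 of 584 ratios kept their direction. These genes were chosen for large ratios, so the count says little about smaller ones. Except where stated, the cause was not tested.

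With no doublets left out, the ratio of the endothelial-like share was 0.662 in aged against young and 1.19 in D+Q against aged. The thick ascending limb-like ratio in D+Q against aged was 1.37 with at least 500 genes per cell. The connecting tubule and principal cell-like ratio in aged against young was 0.448 at a mitochondrial limit of 25%, 0.454 with at least 500 genes and, reversed, 2.45 at a resolution of 2. These settings left 43, 41 and 38 aged cells of the class, and the last 21 young cells, under the minimum of 50. In that class and comparison, transport genes reversed to 0.17, 0.25 and 0.38 and mitochondrially encoded genes to −0.22, −0.50 and −0.16 under these settings, injury genes to −0.26 with at least 500 genes, and matrix genes to −0.10 at a resolution of 2. The Ltc4s log2 ratio in that class reversed to 2.57 in D+Q against aged with at least 500 genes.

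In proximal tubule-like cells, aged against young, the senescence median was 0.15 in clusters 0, 5 and 8. The secretory median was −0.16 at a resolution of 2, 0.18 without a floor, −0.14 without cluster 4 and −0.21 in clusters 0, 5 and 8. Fatty acid oxidation stood at −0.27 under median-of-ratios scaling, −0.28 under TMM and −0.23 without mitochondrially encoded genes in the total. The respiratory chain reversed to 0.037 at a mitochondrial limit of 25%. Ribosomal proteins reversed to −0.0126 at a resolution of 2, −0.0127 as a mean over cells, −0.0059 without cluster 4 and −0.14 in clusters 0, 5 and 8. The macrophage list reversed to 0.81 without a floor, which adds members with few counts.

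In D+Q against aged, the secretory median was 0.28 at a resolution of 2, 0.29 in clusters 0, 5 and 8 and, reversed, −0.074 without a floor. Injury genes stood at −0.31 with each library clustered alone, transport reversed to 0.0147 under median-of-ratios and 0.0139 under TMM scaling, which shift all genes alike, fatty acid oxidation stood at −0.065 in clusters 0, 5 and 8, and the macrophage list reversed to −0.21 without a floor. The percent nearer to young was 27.1 at 2-fold.

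The Cdkn1a share in young cells was 0.271% at a mitochondrial limit of 25%, 0.290% at a resolution of 2, 0.165% thinned to 500 UMIs and 0.908% unthinned. It was 0.731% in aged unthinned, and 0.196% (500 UMIs) and 1.02% (unthinned) in D+Q, so depth limits it. Each thinned share rests on 1 random draw of UMIs. At a resolution of 2 the class held 4826 young cells, beside 4847 in the main setting. Part of the change from 0.474% to 0.290% can therefore come from the draw. An endothelial-like class was not obtained when the aged and D+Q libraries were clustered alone, and at a resolution of 2 only 13 aged cells were in it, so no value is given there.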

Other observations

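The circadian test and the test of shared counting error in the aged library were chosen only after the results were seen. Some core clock genes differed in proximal tubule-like cells in opposite directions between the comparisons. In aged against young, Npas2 was at −1.31 and Arntl at −1.03, while Nr1d1, their repressor, was at 1.11. In D+Q against aged, Npas2 was at 1.72, Arntl at 1.42 and Nr1d1 at −1.15. Fkbp5, a glucocorticoid-responsive gene of the circadian list, was at 0.85 and −0.13. The circadian list's median was 0.23 (0.14 to 0.31) and 0.02 (−0.06 to 0.10), with 4 of 18 members at least 1.5-fold higher and 2 lower in the first comparison, and 3 higher and 1 lower in the second. Clock, at 0.02 and −0.02, and the repressor Cry1, at 0.03 and 0.74, did not follow Npas2 and Arntl in the first.

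Brd1, followed in other classes after its proximal tubule value was seen, was higher in D+Q than in aged in each of them, beside the proximal tubule transcripts counted there. Brd1 was at 1.79 in endothelial-like, 1.28 in thick ascending limb-like, 2.23 in distal convoluted tubule-like and 1.92 in connecting tubule and principal cell-like cells.

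Injury-list genes Krt19, S100a6, Krt18 and Anxa2 were lower in aged than in young proximal tubule-like cells. In cells matched on UMIs and mitochondrial share the median of these genes stayed at −2.85 (−2.95 to −2.69). The 4 genes were chosen for low ratios in these same libraries, and summed counts are scaled by the class total. Matching on depth could therefore hardly move this median, and the result says little about depth as a cause. Free RNA of urothelial cells may account for much of the lower levels of Krt18, Krt19 and Anxa2, but less for S100a6. Urothelial markers, scaled to each gene, covered 96.0% of the difference as the median of 4 genes (69.7 to 129.6). The values were 82.6% for Krt18, 146.4% for Krt19, 109.4% for Anxa2 and 30.8% for S100a6. Those for Krt19 and Anxa2 exceed the whole difference, so the scaling is rough. S100a6 was at 91.5 CPM in proximal tubule-like and 75.7 CPM in endothelial-like young cells, and at 11.1 and 14.7 CPM in aged ones. How much of the pelvis entered each preparation, and age itself, stay open and untested.

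Fatty acid oxidation genes, 9 in number, were lower in aged proximal tubule-like cells. With 5 strata of the S1 to S3 marker ratio weighted equally, their median was −1.19 (−1.30 to −1.09), beside −1.13 unstratified. As far as these markers read segment, this argues against segment makeup as the cause. Of 12 S3 markers, 4 were themselves at least 1.5-fold higher and 1 lower in aged, so the strata read segment imperfectly. Another circadian phase of the aged library could contribute: 8 clock genes that usually peak near Nr1d1 or Per1 lay 0.95 above Arntl, Npas2, Clock and Cry1, of which 2 differed, in aged against young, and −1.27 in D+Q against aged. Without Cry1, a repressor that peaks nearer to Arntl, the differences were 1.47 and −1.61. The time of collection is not given in the sources used here, so phase, feeding, age and treatment stay open.

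For part of the genes D+Q lay nearer to young than to aged. Shared counting error is argued against as the whole cause. The covariance with separate aged cells for each ratio was −0.0470 (range −0.0486 to −0.0442 over 20 divisions), beside −0.0626 observed. In cells matched on depth and mitochondrial share, 44.7% of genes (range 43.1 to 46.5 over 20 draws) were nearer to young. The highest share with other aged cells in the place of D+Q was 20.4%, but in unmatched cells. No such value was computed in matched cells, which hold fewer counts, so depth and mitochondrial share are not excluded. What is particular to the aged library, including its preparation and collection, was not tested and may contribute, as may the treatment.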
